A study of Escherichia coli with 11 samples.

How the data were processed

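Mature tRNA pools of Escherichia coli MG1655 wildtype and 9 mutant strains were measured by YAMAT-seq, per the labels' protocols. Cultures were grown in LB at 37 °C with shaking at 220 rpm. The labels name early-exponential phase for growth and mid-exponential phase for extraction. From each sample 5 µg of total RNA was deacylated, ligated to Y-shaped adapters, reverse transcribed and amplified by PCR. Per the labels, single-end reads of 150 bases were sequenced in Ploen and in Bangalore, and 1 of the 11 sample records, for wildtype, is titled paired-end. The wildtype sheet of batch 3 names raw files of both read directions, per the file headers. Which libraries came from which site is not stated.

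The deposited values are expected counts in name only: per the file headers they are raw reads per primary tRNA sequence, and every value used was a whole number. Per the file headers, the authors extracted sequences of 80 to 151 bp with Geneious 11.1.4. They aligned these to 49, 50 or 53 reference sequences, depending on the sheet, with up to 10% gaps and 10% mismatch. Reads that matched several sequences equally well were assigned to none, so the counts hold uniquely assigned reads only. The sheets of the 3 batches list 48, 52 and 48 sequences, among them the constructed A34 sequences.

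The tables hold 12 sheets with 3 replicates each, and libraries were assigned to strains by the name of the sheet. Mutant sheets of batch 2 carry a line naming the wildtype, which the sheet names contradict. The edited tRNA was checked in every library first, and it matched the sheet name for the gly and pro strains, ∆thrT and serX(AGA). For the sheet of thrTU(AGU) only the thrT part matched. Thr-UGU, the species of thrU, was still counted there, with a log2 fold change of -0.27 against wildtype. For ∆serX the edited tRNA could not serve as a check, because serW gives Ser-GGA as well and ∆serX replicate 1 lay within the range of wildtype. For the 2 phe strains it could not either, because of the low counts and the second gene, pheU. The 36 columns of counts were used. Another 72 per-sample columns, which repeat these counts or give the authors' proportions of them, were left out, as were the summary lines under the counts. The authors' own proportions for batch 3 leave out fMet and Pro-AGG, and shares here were computed from all listed tRNA sequences.

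Between 329652 and 5278697 reads per library were counted, with a median of 2612333. Each mutant was compared with the wildtype of its own batch (9 comparisons), and each A34 strain that had one with its deletion strain (4 comparisons). Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and all libraries of the batch in the fit. A species was tested if it had at least 10 counts in at least 3 libraries, which left 48, 50 and 47 species. P-values were adjusted by the Benjamini-Hochberg method over the species tested, with a threshold of 0.05. Shares were compared by exact two-sided permutation tests. A count of 0 was given a limit of 3 reads. Tables and figures were made with Python 3.11.15, scipy 1.17.1, numpy 2.4.6 and matplotlib 3.10.9.

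The comparisons, tests, 17 lists of tRNAs and the rule for named species were fixed before the data were examined. Named in each comparison were the edited tRNA with its A34 version, and every other tRNA of that amino acid. Against wildtype, up to 10 further species in each direction were to be named if they passed the threshold with libraries that did not overlap between the groups. No species met that last part, and other names are marked in the text as chosen later. The lists were the Gly, Ser, Pro, Thr and Phe families, the thrU-tyrU-glyT-thrT, glyW-cysT-leuZ and argX-hisR-leuT-proM clusters, tRNAs in rRNA operons, initiator tRNAs, tRNAs reading rare codons, tRNAs with a long variable arm, native tRNAs with A34, and all species with A34, C34, G34 or U34. All 86 gene names given for the species were found in the annotation ASM584v2.

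Whether replicate numbers pair the libraries was checked by correlating the deviations of same-numbered libraries from their group means. Every pair was over 0.1 for ∆thrT against wildtype (lowest 0.615) and for proL(AGG) against wildtype (lowest 0.652). In the other 11 comparisons at least 1 pair was not, though some single pairs were high. Against wildtype, the 3 pairs gave 0.78, 0.08 and 0.60 for serX(AGA) and 0.74, 0.07 and 0.55 for thrTU(AGU). They gave 0.73, -0.13 and 0.58 for pheV(AAA) and 0.73, -0.23 and 0.62 for glyU(ACC), but -0.20, -0.32 and 0.07 for ∆serX. The permutation tests ignore any such partial pairing. The labels do not say what a replicate number marks.

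The fits were also tested on simulated data, with 10 species changed in each of 10 simulations per comparison. The simulated counts had the same spread for every species, with no pairing and no outlying library. Only species with at least 10 expected counts in the smallest library of the batch were changed. The recovery below holds for such data and may be lower in the real libraries. Changes of 4-fold were recovered in 99% to 100% of cases by edgeR and by DESeq2. By edgeR, changes of 2-fold were recovered in 29% (pheV(AAA) against ∆pheV) to 47% (∆thrT against wildtype) in batches 1 and 2, and in 95% for proL(AGG) against wildtype. By DESeq2 they were recovered in 29% (pheV(AAA) against ∆pheV) to 58% (glyU(ACC) against ∆glyU) in batches 1 and 2, and in 97% for proL(AGG) against wildtype. The biological coefficient of variation was 30.8% in batch 1, 30.8% in batch 2 and 20.0% in batch 3.

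Alternatives to the processing were other scaling (DESeq2 size factors, library totals, TMM without the edited family), the test of DESeq2 1.42.0, no count filter or one of 100 counts, and only the 2 compared groups in the fit. Further ones were replicate number as a block, each library left out in turn, a threshold of 1.5-fold, and species summed by anticodon. For shares, the denominator and the scaling were varied. After the data were seen, 4 alternatives were added: leaving out a doubted library (∆glyU replicate 3 or ∆thrT replicate 2), leaving out constructed sequences that neither strain carries, leaving out wildtype libraries in turn between batches, and comparing shares within pairs of same-numbered libraries where the numbers went together (exact sign-flip test).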

Results

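Pools of mature transfer RNA (tRNA) were sequenced from Escherichia coli MG1655 and 9 strains derived from it. The assay, YAMAT-seq, ligates a Y-shaped adapter to the CCA end that mature tRNAs carry, so that full-length molecules enter the library. Per the labels, 5 of the strains carry a tRNA gene changed so that its anticodon starts with adenine (A34). In the other 4 a tRNA gene had been deleted, again per the labels. The A34 strains are labelled glyU(ACC), serX(AGA), thrTU(AGU), pheV(AAA) and proL(AGG), and the deletions ∆glyU, ∆serX, ∆thrT and ∆pheV. The libraries came in 3 batches, each with its own wildtype. Batch 1 held the glyU strains, batch 2 the serX, thrT and pheV strains, and batch 3 proL(AGG). Each strain had 3 libraries per batch, which gave 36 libraries in all and 9 of wildtype. The sources used here do not say that the replicates of a strain were separate cultures, so p-values measure the spread between these libraries, which may be technical.

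Between 329652 and 5278697 reads per library were counted to a tRNA, with a median of 2612333. The library with the fewest was ∆thrT replicate 2. Reads were counted per tRNA species, meaning each distinct tRNA sequence, named here by amino acid and anticodon. Genes with identical sequences share a species, and a number after the anticodon separates sequences with the same anticodon. Levels are shares of all counted tRNA reads, given as mean ± SD with n = 3. Intervals and limits from read numbers cover counting error only, because PCR copies of a molecule cannot be told from separate molecules.

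The first set of comparisons asked what replaced the tRNA of glyU, the gene for the tRNA-Gly with anticodon CCC, when its anticodon was changed to ACC. In glyU(ACC), Gly-CCC fell from 0.807% ± 0.096 in wildtype to 0.00199% ± 0.00055, and Gly-ACC rose to 0.849% ± 0.066. The fitted log2 fold changes were -8.58 (SE 0.46) for Gly-CCC and 10.34 (SE 0.52) for Gly-ACC, and edgeR gave each an adjusted p of 6.2e-07. Gly-ACC in the mutant stood at 105% of the level of Gly-CCC in wildtype, a difference within the spread between replicates (exact two-sided permutation test, p = 0.5, n = 3 per group, where the smallest possible p is 0.1). Similar read shares of different sequences need not mean similar amounts, here or for the genes below, because no known amounts were sequenced. In the reference annotation ASM584v2, glyU lies between ygeQ and actS.

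The other tRNA-Gly species were Gly-GCC and Gly-UCC, which had log2 fold changes of 0.18 (95% interval -0.36 to 0.73) and 0.085 (-0.91 to 1.08) in glyU(ACC). Neither passed the test, and the second turned to -0.060 without wildtype replicate 1 and also turned sign without wildtype replicate 2. All tRNA-Gly together made up 30.7% ± 2.2 of the pool in glyU(ACC) and 28.6% ± 4.7 in wildtype (exact permutation p = 0.5). Gly-CCC and Gly-ACC were the 2 species past the threshold of 48 tested, and DESeq2 called 2 as well. With the 2 groups alone in the fit, without ∆glyU, edgeR called 6.

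In ∆glyU, reads of Gly-CCC numbered 2, 0 and 2 in the 3 libraries, against 18159, 30474 and 40426 in wildtype (fitted log2 fold change -13.92, SE 0.60, edgeR adjusted p = 1.91e-07, no bound at such counts). A count of 0 in the second library allows a share of up to 0.000109%. Gly-ACC, a sequence that neither strain encodes, had 12, 23 and 41 reads in wildtype and 0, 2 and 2 in ∆glyU, a call with a log2 fold change of -3.71 (SE 0.61, adjusted p = 0.00478). Gly-GCC and Gly-UCC did not pass the test, at 0.028 (-0.52 to 0.58) and 0.62 (-0.38 to 1.62), and all tRNA-Gly made up 28.0% ± 5.2 of the pool (exact permutation p = 0.9). The sign for Gly-GCC turned under most alternatives, DESeq2 scaling and library totals among them, and that for Gly-UCC without ∆glyU replicate 3. That library stood apart from its group, with 4 reads of Leu-GAG against 1439 and 761. No other species passed of 48 tested, with 3 at an unadjusted p under 0.05.

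Set against the deletion, glyU(ACC) had more reads counted to both glyU sequences. Gly-ACC was higher by 14.06 (SE 0.64, edgeR adjusted p = 2.74e-07) and Gly-CCC by 5.34 (SE 0.54, adjusted p = 0.000124) on the log2 scale. The Gly-CCC reads of glyU(ACC) numbered 38, 68 and 80, or 0.183% to 0.277% of its Gly-CCC and Gly-ACC reads. In wildtype, which does not encode Gly-ACC, reads of Gly-ACC stood at 0.0661% to 0.101% of those of Gly-CCC. Whether the Gly-CCC reads of glyU(ACC) are misassigned reads of Gly-ACC was not tested. Gly-GCC and Gly-UCC had values of 0.15 (-0.39 to 0.70) and -0.54 (-1.53 to 0.46). Leaving out ∆glyU replicate 2 raised the number of called species from 2 to 8. Without ∆glyU replicate 3, Gly-UCC had the opposite sign, at 0.21, and without ∆glyU replicate 1 Gly-GCC did, at -0.016.

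**Figure D1:**
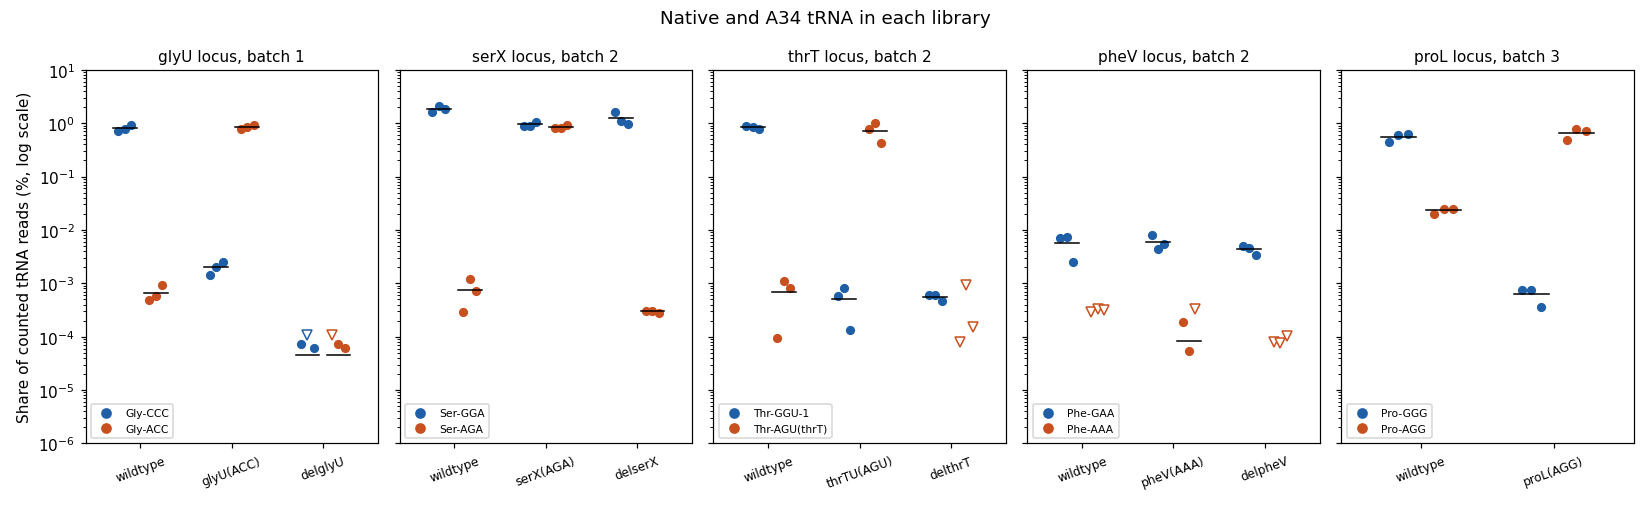
Share of counted tRNA reads in percent (log scale) of the native sequence (blue) and the A34 sequence (orange) of each edited gene, in each library of wildtype, the A34 strain and the deletion (written del), with black lines at the mean of 3 libraries and open triangles at the limit of 3 reads for libraries without reads. In proL(AGG) the A34 sequence held 0.658% of reads and the native one 0.000622%, while in pheV(AAA) the native Phe-GAA stayed at 0.00591%.

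For serX, the question was the same with anticodon AGA in place of GGA. The genes serX and serW give the same mature sequence, counted as Ser-GGA, so loss of serX leaves a second gene for it. In serX(AGA), Ser-AGA rose to 0.853% ± 0.071 from a background of 0.000742% ± 0.00046 in wildtype, where it had 3, 11 and 7 reads. Ser-GGA fell from 1.85% ± 0.24 to 0.953% ± 0.088, which is 51.5% of its wildtype level. The log2 fold changes were 10.14 (SE 0.68, edgeR adjusted p = 2.67e-10) and -1.02 (SE 0.23, adjusted p = 0.0060). Ser-AGA and Ser-GGA together held 1.81% ± 0.16, which did not differ from wildtype Ser-GGA beyond the spread (exact permutation p = 0.9).

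The other tRNA-Ser species did not pass the test in serX(AGA): Ser-CGA at -0.48 (-1.24 to 0.29), Ser-GCU at -0.17 (-0.97 to 0.62) and Ser-UGA at -0.040 (-0.70 to 0.62). The sign for Ser-UGA was positive under most alternatives, DESeq2 scaling and library totals among them. All tRNA-Ser held 2.27% ± 0.31 against 2.35% ± 0.40 (exact permutation p = 0.9). One more species was called lower, the constructed Thr-AGU(thrT), which neither strain encodes. It had 3, 2 and 2 reads against 1, 10 and 8 (log2 fold change -2.65, SE 0.73, adjusted p = 0.0335) and was chosen for mention after its values were seen. The call of Ser-GGA was lost without serX(AGA) replicate 1 (log2 fold change -0.87, adjusted p = 0.0975) or wildtype replicate 2 (-0.89, adjusted p = 0.0662). Over 17 alternatives its log2 fold change ran from -1.09 to -0.87 and its adjusted p from 0.000708 to 0.0975, with 15 under the threshold, and the call of Thr-AGU(thrT) was made in 6 of 17.

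In ∆serX, Ser-GGA held 1.24% ± 0.35, or 66.9% of wildtype, with a log2 fold change of -0.69 (SE 0.23) that edgeR did not call (adjusted p = 0.110). DESeq2 called it (adjusted p = 0.0486), and over 17 alternatives the adjusted p ran from 0.0486 to 0.775. In ∆serX replicate 1, Ser-GGA lay within the range of wildtype. Without that library the log2 fold change was -0.89, and without wildtype replicate 2 it was -0.52. Ser-AGA background was 11, 10 and 4 reads (log2 fold change -1.35, SE 0.66, adjusted p = 0.459). Ser-CGA, Ser-GCU and Ser-UGA had values of -0.34 (-1.09 to 0.42), -0.023 (-0.81 to 0.77) and 0.10 (-0.55 to 0.76), and each changed sign under some alternative, Ser-GCU under most. All tRNA-Ser held 1.77% ± 0.47 (exact permutation p = 0.2). No species of 50 passed in edgeR, against 5 at an unadjusted p under 0.05 and 2 by DESeq2, and 1 passed without wildtype replicate 1, Thr-AGU(thrT).

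Between serX(AGA) and ∆serX, Ser-AGA was higher by 11.49 (SE 0.71, edgeR adjusted p = 5.79e-11) and was the 1 species called by either tool. Ser-GGA differed by -0.33 (95% interval -0.81 to 0.14, adjusted p = 0.98), so that no difference in it between the A34 strain and the deletion was shown. Ser-CGA, Ser-GCU and Ser-UGA had values of -0.14, -0.15 and -0.14, with the signs of the last 2 changing when some single libraries were left out.

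The thr strains concerned thrT, a gene for a tRNA-Thr with anticodon GGU, which the annotation places next to glyT in a cluster with thrU and tyrU. The series describes thrTU(AGU) as expressing thrT(AGU) in place of both thrT and thrU. In the strain labelled thrTU(AGU), Thr-GGU-1 fell from 0.848% ± 0.052 to 18, 21 and 2 reads (log2 fold change -10.73, SE 0.55, edgeR adjusted p = 1.75e-12). Thr-AGU(thrT) rose to 0.728% ± 0.29 (10.02, SE 0.62, adjusted p = 1.96e-10), which was not separable from wildtype Thr-GGU-1 (exact permutation p = 0.7). Thr-UGU, the species of thrU, held 3.15% ± 1.1 against 3.37% ± 1.7 in wildtype, with a log2 fold change of -0.27 (95% interval -1.26 to 0.72, adjusted p = 0.98).

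Thr-GGU-2, Thr-CGU and the constructed Thr-AGU(thrU) had values of -0.26 (-1.05 to 0.53), -0.073 (-0.92 to 0.78) and -0.88 (-2.11 to 0.36), and none passed. The sign for Thr-CGU turned under most alternatives, DESeq2 scaling and library totals among them. That for Thr-UGU turned without replicate 3 of the mutant (0.16) or wildtype replicate 1 (0.46). All tRNA-Thr held 6.42% ± 1.4 against 6.91% ± 2.0 (exact permutation p = 0.8). Outside the tRNA-Thr, Gln-CUG was called lower at -0.52 (SE 0.15, adjusted p = 0.0466), with libraries that overlapped wildtype. It was chosen for mention after its values were seen, and the call was made in 2 of 17 alternatives. In all, 3 species of 50 passed in edgeR and 2 in DESeq2.

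In ∆thrT, Thr-GGU-1 fell to 23, 2 and 9 reads (-10.67, SE 0.56, adjusted p = 2.99e-12). Thr-AGU(thrT) had no reads in ∆thrT, against 1, 10 and 8 in wildtype. The pooled wildtype share was 13.2-fold above a limit of 3 reads over the ∆thrT group. Without ∆thrT replicate 1, the deepest of the 3 libraries, it was 4.96-fold above. These ratios take the few wildtype reads as exact and are no lower bounds. In ∆thrT replicate 2 alone the limit, 0.00091%, lay above the wildtype mean of 0.000676%. Thr-UGU, Thr-GGU-2, Thr-CGU and Thr-AGU(thrU) did not pass, at -0.57 (-1.56 to 0.42), -0.057 (-0.84 to 0.73), -0.31 (-1.16 to 0.54) and -0.74 (-2.02 to 0.53). The sign for Thr-GGU-2 turned under most alternatives, DESeq2 scaling and library totals among them. Those for Thr-UGU and Thr-CGU turned without wildtype replicate 1, and that for Thr-CGU also without ∆thrT replicate 2. All tRNA-Thr held 5.13% ± 2.2 (exact permutation p = 0.4), a test that ignores the pairing described next.

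Those 2 species were the calls of edgeR and of DESeq2 in ∆thrT, with 7 at an unadjusted p under 0.05. Replicate numbers of ∆thrT and wildtype went together, and a fit with the number as a block called 3, the third being Gln-CUG at -0.51 (SE 0.14, adjusted p = 0.0350, unblocked 0.0522). Without wildtype replicate 2 the count was 4. Within pairs of same-numbered libraries, a comparison chosen after the data were seen, all tRNA-Thr differed by -1.43, -1.63 and -2.28 percentage points (mean -1.78, SD 0.44), and Thr-UGU by -1.02, -0.92 and -0.73 (mean -0.89, SD 0.15). The tRNA-Thr other than Thr-GGU-1 and Thr-AGU(thrT) differed by -0.54, -0.77 and -1.48 (mean -0.93, SD 0.49). The exact sign-flip test gave p = 0.25 for each, the smallest possible with 3 pairs. Thr-UGU passed in none of the 17 edgeR and DESeq2 alternatives, the blocked fit included (adjusted p from 0.124 to 0.990).

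Between the strain labelled thrTU(AGU) and ∆thrT, Thr-AGU(thrT) was the 1 species called by either tool (edgeR adjusted p = 4.55e-11). Its pooled share in the A34 strain, taken as exact, was 15849-fold above the limit of 3 reads over the ∆thrT libraries. Without ∆thrT replicate 1 it was 5948-fold above. Thr-GGU-1 differed by -0.068 (95% interval -1.11 to 0.97) and Thr-UGU by 0.30 (-0.69 to 1.29), neither past the threshold. Thr-GGU-2, Thr-CGU and Thr-AGU(thrU) had values of -0.20, 0.24 and -0.13. The signs of Thr-GGU-1, Thr-CGU and Thr-AGU(thrU) each turned when some single library was left out.

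For pheV, a gene for tRNA-Phe with anticodon GAA whose sequence is shared with pheU, very few reads were recovered in any strain. Phe-GAA held 0.00591% ± 0.0019 in pheV(AAA), 0.00432% ± 0.00088 in ∆pheV and 0.00560% ± 0.0027 in wildtype. The log2 fold changes against wildtype were 0.019 (95% interval -0.78 to 0.82) and -0.44 (-1.24 to 0.36), and between the A34 strain and the deletion 0.46 (-0.32 to 1.25), so that a 2-fold change was not excluded in 2 of these 3. The first value changed sign without pheV(AAA) replicate 1 (-0.21) or wildtype replicate 3 (-0.29). Phe-AAA had 10, 1 and 0 reads in pheV(AAA) and none in wildtype or ∆pheV, where a count of 0 over the group allows up to 0.000103% and 2.83e-05%. It lay below the count filter and was not tested.

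No species of 50 passed in edgeR or in DESeq2 in pheV(AAA) or ∆pheV against wildtype, or between them. At an unadjusted p under 0.05 edgeR gave 1, 2 and 1 species.

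For proL, the gene for the tRNA-Pro with anticodon GGG, the labels give an A34 strain and no deletion. The wildtype sheet of this batch names raw files of both read directions, per the file headers. The labels do not title the proL(AGG) record paired-end. Read layout may thus differ along with genotype in this comparison, and its effect was not tested. In proL(AGG), Pro-GGG fell from 0.559% ± 0.099 to 8, 7 and 4 reads (log2 fold change -9.75, SE 0.31, edgeR adjusted p = 2.16e-10), and Pro-AGG rose to 0.658% ± 0.16 (4.89, SE 0.24, adjusted p = 9.16e-09). Pro-AGG in the mutant did not differ from Pro-GGG in wildtype beyond the spread (exact permutation p = 0.4), a test that ignores the pairing of these libraries. Within pairs of same-numbered libraries it was higher by 0.033, 0.17 and 0.092 percentage points (mean 0.0996, SD 0.071, exact sign-flip p = 0.25, again the smallest possible). Its background in wildtype was 190, 243 and 161 reads, or between 3.92% and 4.44% of the Pro-GGG reads, where the A34 sequences of glyU, serX and thrT stood between 0.0106% and 0.129% of theirs. Pro-CGG and Pro-UGG did not pass, at 0.19 (-0.15 to 0.53) and 0.058 (-0.30 to 0.42), the second turning sign without proL(AGG) replicate 2 (-0.074) or wildtype replicate 3 (-0.015).

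All tRNA-Pro held 1.75% ± 0.28 in proL(AGG) against 1.64% ± 0.10 (exact permutation p = 0.5, and 0.5 by the sign-flip test within pairs). Of 47 species 2 passed in edgeR and 2 in DESeq2. Replicate numbers went together here as well, and a blocked fit called 3, the third being Lys-UUU at 0.28 (SE 0.084, adjusted p = 0.0209, unblocked 0.999), chosen for mention after its values were seen. Leaving out any one wildtype library left too few libraries with 10 reads of Pro-GGG, so the species was then not tested and the count was 1.

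**Figure D2:**
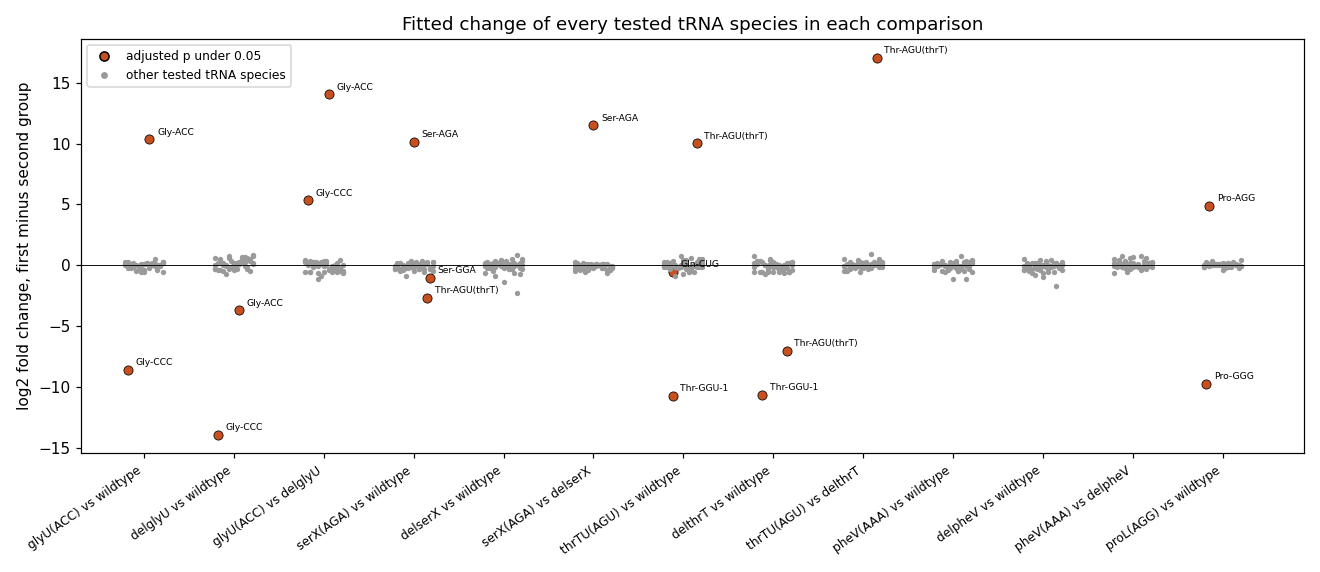
Fitted log2 fold change of every tested tRNA species, one column of points for each of the 13 comparisons (deletions written del), with the species at an adjusted p under 0.05 drawn larger in orange and named, and all others in grey. Fitted values for sequences with no reads in one group are no bounds. The named points are mostly the native and A34 sequences of the edited gene, and the smallest of them is Gln-CUG at -0.52.

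Native species outside the edited amino acid passed the unblocked edgeR test in 1 of the 13 comparisons, as Gln-CUG. Their largest absolute log2 fold change lay between 0.42 in proL(AGG) against wildtype and 1.11 in glyU(ACC) against ∆glyU. Outside the family the 95% intervals reached, in the median, this far to either side: 0.66 in glyU(ACC) against wildtype, 0.64 in the strain labelled thrTU(AGU) against wildtype and 0.38 in proL(AGG). Constructed sequences included, the intervals reached past 2-fold for 12 of 44, 16 of 44 and 3 of 43 species in these comparisons. In ∆thrT against wildtype they did so for 23 of 44. Changes of 2-fold were thus not excluded for these species.

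Among the groups of tRNAs fixed beforehand, no member passed in any comparison in the glyW-cysT-leuZ or argX-hisR-leuT-proM clusters, the tRNAs encoded in rRNA operons (such as Ala-UGC and Ile-GAU), the initiator tRNAs or the tRNAs with U34, counted over all species or adjusted over the list alone. In the thrU-tyrU-glyT-thrT cluster 1 of 6 members fell in the strain labelled thrTU(AGU) and 1 of 6 in ∆thrT, Thr-GGU-1 each time. Of the 5 measured tRNAs that read rare codons 1 fell in proL(AGG), Pro-GGG. Among 14 tRNAs with a long variable arm, Ser-AGA rose and Ser-GGA fell in serX(AGA). The counts by amino acid and by A34, C34 and G34 held the calls given above for each strain.

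Adjusting over the list alone gave the same counts except in 3 strains. In ∆glyU it added Arg-ACG, the 1 native tRNA with A34, at 0.79 (SE 0.24, adjusted p = 0.0102 over the list alone and 0.163 over all species). In ∆serX it added Ser-GGA among the tRNA-Ser (adjusted p = 0.0330) and Thr-AGU(thrT) among the tRNA-Thr (0.0207) and the A34 species (0.0138). In ∆thrT it added Gln-CUG among the C34 species (0.0470).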

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

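All tests of explanations in this part, with their bounds, were chosen only after the result was seen. Sequences below the count filter were examined for signals after the data were seen, and both that follow were picked out because a mutant held more reads than its wildtype, as a share of counted reads over the 3 libraries together and beyond the limit of 3 reads where wildtype had fewer.

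Phe-AAA had 11 reads in pheV(AAA), as 10, 1 and 0 in the 3 libraries, and none in wildtype or ∆pheV. They made up 1.96% of the tRNA-Phe reads of pheV(AAA) (exact 95% interval 0.981% to 3.48%), against 1 of 2463 in the other 18 libraries of the batch (upper limit 0.226%). Replicate 1 gave 10 of the 11 reads, and without it the share was 0.775% (1 of 129, interval 0.0196% to 4.24%). Too few tRNA-Phe reads to see an A34 version as frequent as the native one was argued against, since the upper limit was at most 7.40% in any of the 3 libraries. Libraries of another strain under this label stayed open, with 1 of the 3 libraries above the upper limit of the other strains. Poor capture or alignment of the A34 version also stayed open at 1.96%, because no known amounts were sequenced. A low level of the A34 tRNA in the cell is a hypothesis that the tables give no way to separate from these. Conversion of A34 to inosine that is read as G, and so counted as Phe-GAA, was not tested for pheV.

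Ile2-CAU-1 had 28 reads in proL(AGG), as 6, 6 and 16, against 0, 2 and 16 in the wildtype of that batch. The mean shares were 0.000877% and 0.000883%, so the means of the libraries showed no excess. The difference was not tested, and no biological explanation was tested.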

How the results depend on the processing

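No tests of explanations stand in this part, and the alternatives marked as added were chosen only after the result was seen. Over all alternatives, 391 values that answer a comparison stayed, where a count stays if it is within 1.5 times the reported one, 15 counts moved beyond that and 13 shares reversed. Of 271 counts of called species 71 differed from the reported one at all, many by the loss of Gln-CUG, called in 2 of 17 alternatives, or of Thr-AGU(thrT) in serX(AGA), called in 6 of 17. Of single species, 764 values stayed, 84 reversed, 2 weakened and 1 strengthened. Reversed values were all of differences that had not passed. With edgeR most 2-fold changes were missed in simulated data of batches 1 and 2, and whether depth limits the calls was not tested. Scaling moved the median log2 fold change by up to 0.13 (∆thrT against wildtype, DESeq2). Where no other reason is given, the cause was not tested.

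Counts of called species: with only the 2 groups compared in the fit (fewer libraries for the spread), 6 for glyU(ACC) against wildtype. In the same setting, 1 for ∆thrT against wildtype, where Thr-AGU(thrT) fell under the count filter. Summed by anticodon (Thr-GGU-1 joins Thr-GGU-2, and Thr-AGU(thrT) joins Thr-AGU(thrU)), 1 for the strain labelled thrTU(AGU) against wildtype and 0 for ∆thrT against wildtype. Constructed sequences of neither strain left out (added), 1 for ∆glyU and 1 for ∆thrT against wildtype. This setting removes the called Gly-ACC and Thr-AGU(thrT) themselves, so the lower counts follow from the setting. DESeq2 gave 2 for ∆serX against wildtype.

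The replicate block moved the count from 2 to 3 for ∆thrT and for proL(AGG) against wildtype and from 3 to 2 for serX(AGA) against wildtype, and changed no other count. Where numbers went together, all 6 libraries correlated best with their own number, a hint from the data and not the design. Within pairs (added), the tRNA-Thr share of ∆thrT against wildtype had a mean log2 ratio of -0.48 and the tRNA-Pro share of proL(AGG) against wildtype 0.079. With the block, Ser-GCU in ∆serX against wildtype turned to 0.066.

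Log2 values that reversed, by setting. DESeq2 size factors: Gly-GCC ∆glyU against wildtype -0.071, Ser-UGA serX(AGA) against wildtype 0.0495, Thr-CGU thrTU(AGU) against wildtype 0.022, Thr-GGU-2 ∆thrT against wildtype 0.069. The DESeq2 test, same order: -0.071, 0.0503, 0.022, 0.069. Library totals, same order: -0.058, 0.040, 0.071, 0.030, and Ser-GCU ∆serX against wildtype 0.064. At least 100 counts, same order: -0.029, 0.011, 0.069, 0.072, 0.031. Only the 2 groups, first 4: -0.023, 0.034, 0.017, 0.12. No count filter: Ser-UGA 0.029, Thr-CGU 0.041, Thr-GGU-2 0.074, Ser-GCU 0.067. Summed by anticodon: Ser-UGA 0.041. TMM without the edited family: Ser-UGA 0.074, Ser-GCU 0.035. Constructed sequences of neither strain left out (added): Gly-GCC -0.023, Thr-CGU 0.016, Thr-GGU-2 0.12, Ser-GCU 0.087. TMM-normalized: Gly family share ∆glyU against wildtype 0.060.

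Doubted library left out (added; not given for batch 3): Gly-UCC ∆glyU against wildtype -0.13 and glyU(ACC) against ∆glyU 0.21, Ser-UGA serX(AGA) against wildtype 0.029, Ser-GCU ∆serX against wildtype 0.067, Thr-CGU thrTU(AGU) against wildtype 0.041, ∆thrT against wildtype 0.054 and thrTU(AGU) against ∆thrT -0.014, Thr-GGU-2 ∆thrT against wildtype 0.11.

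Leaving out each library in turn, lowest and highest. glyU(ACC) against wildtype: Gly-UCC -0.060 and 0.35. ∆glyU against wildtype: Gly-GCC -0.16 and 0.24, Gly-UCC -0.13 and 0.95, family share -0.16 and 0.11. glyU(ACC) against ∆glyU: count 2 and 8, Gly-GCC -0.016 and 0.34, Gly-UCC -0.86 and 0.21. serX(AGA) against wildtype: count 1 and 3, Ser-GCU -0.53 and 0.10, Ser-UGA -0.099 and 0.15, family share -0.18 and 0.058. ∆serX against wildtype: count 0 and 1, Ser-CGA -0.40 and 0.0054, Ser-GCU -0.19 and 0.27, Ser-UGA -0.23 and 0.34. serX(AGA) against ∆serX: Ser-GCU -0.50 and 0.035, Ser-UGA -0.33 and 0.19. thrTU(AGU) against wildtype: Thr-CGU -0.31 and 0.38, Thr-UGU -0.49 and 0.46, family share -0.24 and 0.15. ∆thrT against wildtype: count 2 and 4, Thr-CGU -0.87 and 0.16, Thr-GGU-2 -0.20 and 0.14, Thr-UGU -1.24 and 0.15, and, with no change of sign, Thr-AGU(thrU) -2.13 and -0.19. thrTU(AGU) against ∆thrT: Thr-CGU -0.014 and 0.80, Thr-GGU-1 -0.54 and 0.27, Thr-AGU(thrU) -0.60 and 1.26. pheV(AAA) against wildtype: Phe-GAA -0.29 and 0.35, edited tRNA share -0.27 and 0.31, family share -0.25 and 0.33. proL(AGG) against wildtype: count 1 and 2 (the count filter then removes Pro-GGG), Pro-UGG -0.074 and 0.16, family share -0.013 and 0.21.

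Between wildtype batches counts stayed within 1.5 times, but the split into higher and lower moved: for 1 against 2 from 11 and 14 to 18 and 13 with DESeq2 size factors, and with library totals for 1 against 3 from 15 and 16 to 7 and 24 and for 2 against 3 from 15 and 11 to 11 and 24.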

Other observations

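The tests of explanations in this part, and the splits of the libraries, were chosen only after the result was seen. In wildtype, a few species held most of the reads, and which ones depended on the batch. In batch 1 Gly-GCC held 25% ± 4.0, followed by Ala-UGC (10.2%), Asp-GUC (8.65%), Glu-UUC (7.62%) and Val-UAC (7.05%), and the first 10 species held 80.3%. In batch 2 the first were Asp-GUC (14.4%), Gln-CUG (14.0% ± 2.3), Gln-UUG (9.78%), Gly-GCC (9.17%) and Asn-GUU (7.52%), with 79.1% in 10 species. In batch 3 they were Ala-UGC (12.9%), Asp-GUC (12%), Val-UAC (8.85%), Gly-GCC (6.05%) and Gln-CUG (5.61%), with 67.0% in 10.

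Between wildtype libraries of batches 1 and 2, edgeR called 25 of 47 species, between 1 and 3 it called 31, and between 2 and 3 it called 26. The initiator species fMet-CAU-1 held 0.259%, 0.0797% and 3.63% in the 3 batches (batch 2 minus 3, log2 -4.62, SE 0.32). Gly-UCC held 2.83%, 0.570% and 0.325%, and Gly-GCC differed between batches 1 and 3 by 2.82 (SE 0.22) on the log2 scale. These species were chosen after their values were seen. These values depend on the scaling: the plain shares give a log2 ratio of -5.51 for fMet-CAU-1 and 2.04 for Gly-GCC. The file headers give differences in processing between the batches: raw files of both read directions for the wildtype of batch 3 only, and 50, 53 and 49 reference sequences for the wildtype of batches 1, 2 and 3. Their effect was not tested, and no biological explanation was tested.

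Gln-CUG, also chosen after its values were seen, held 14.0% ± 2.3 in wildtype of batch 2 and less on average in all 6 mutants of that batch: 12% in serX(AGA), 11% in ∆serX, 10.6% in the strain labelled thrTU(AGU), 10.4% in ∆thrT, 10.8% in pheV(AAA) and 12.1% in ∆pheV. The same 3 wildtype libraries, from 11.5% to 16.1%, enter every one of these differences.

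In wildtype and the deletions, Gly-ACC had 12, 23 and 41 reads in wildtype and 0, 2 and 2 in ∆glyU, and Thr-AGU(thrT) had 1, 10 and 8 in wildtype and none in ∆thrT. Thr-AGU(thrT) also had a lower mean share in strains that keep thrT, at 0.000119% in serX(AGA) (3, 2 and 2 reads), 0.000129% in ∆serX (7, 4 and 1), 0.000199% in ∆pheV (9, 6 and 6) and 0.000378% in pheV(AAA) (10, 5 and 6), against 0.000676% in wildtype.

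Thr-UGU was present in the strain labelled thrTU(AGU), which is described as lacking thrU. Reads of thrT(AGU) assigned to Thr-UGU were argued against, since at most 0.0810% went to the closer Thr-GGU-1. Reads of an intact strain mixed in were argued against by Thr-GGU-1 at 0.0593% of wildtype. A log2 fold change of -0.27 went with thrU still being present in the sequenced cultures, and the labels alone do not settle which construct was sequenced.

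Pro-AGG had 190, 243 and 161 reads in the wildtype of batch 3. Even exchange of reads with the proL(AGG) libraries was argued against, since Pro-GGG in proL(AGG) stood at 0.111% of wildtype. Native reads assigned to the A34 sequence (at least 3.92% of Pro-GGG) and one-way carry-over from proL(AGG) (3.51% of its level there) both stayed open. The raw files of both read directions named for this wildtype were not tested as a cause. No biological explanation was tested.

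As a hypothesis, A34 could be converted to inosine and be read as G. At most 0.156% of the G34 and A34 reads were G34 in the 6 libraries of proL(AGG) and the strain labelled thrTU(AGU), which argued against most molecules being read that way. For serX, no serX(AGA) library exceeded any ∆serX library in Ser-GGA by more than 0.0815% of counted reads, where Ser-AGA held at least 0.805%, which argued against it too if serW gives as much Ser-GGA in both strains and the ∆serX label holds. For glyU the test was not possible, because Gly-CCC is not G34. For pheV it was not made, and the hypothesis stayed open there. A34 read as G would count as Phe-GAA, which pheU gives as well. Phe-GAA in pheV(AAA) stood at 106% of wildtype and 137% of ∆pheV (exact permutation p = 0.9 and 0.3).

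The 6 libraries of each comparison can be split into 3 and 3 in 10 ways, so a share under 0.05 cannot be reached. Most calls between strains are the edited sequences, which differ by construction. A mixed split loses them and also puts the difference between the groups into the spread of the fit. The splits therefore give no measure of chance. The real split called more species than every other split in 8 comparisons: glyU(ACC) against wildtype (2, highest other 0), ∆glyU against wildtype (2 and 1), glyU(ACC) against ∆glyU (2 and 0), serX(AGA) against wildtype (3 and 1), serX(AGA) against ∆serX (1 and 0), the strain labelled thrTU(AGU) against wildtype (3 and 1) and against ∆thrT (1 and 0), and proL(AGG) against wildtype (2 and 0). For ∆thrT against wildtype 3 of the 10 splits, the real one included, called at least as many (2, highest other 2). The splits were fitted without a block, so they ignore the pairing of replicate numbers in this comparison and in proL(AGG) against wildtype. For ∆serX, pheV(AAA) and ∆pheV against wildtype and pheV(AAA) against ∆pheV the real split called 0, so that all 10 did, with a highest other of 0, 1, 0 and 0. Between wildtype batches 1 split of 10 did in each case (25, 31 and 26 species, highest other 0).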
